A study of Drosophila melanogaster with 3 samples.

How the data were processed

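Grain was profiled by ChIP-seq in 3 biological replicates of transgenic Drosophila melanogaster embryos aged 0 to 24 h, with an antibody against the GFP tag. Chromatin was sheared by sonication into fragments of 200 to 800 bp, per the labels. The deposited files are peak lists in the narrowPeak format, with the assemblies dm6 and dm3 named per the file descriptions deposited with them. Each replicate's list was derived by the authors from that replicate's alignments and a control file, and the pooled list from the alignments of all 3 replicates and a control file. The optimal list was derived from these lists by the irreproducible discovery rate method. The aligner, the peak caller, their versions and the settings of the discovery rate test are not given in the sources used here, and the control was not analysed here.

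In these lists the authors give each peak a signal value, whose scale is not stated and which is set separately in each list, and a −log10 q-value, which the deposited lists hold capped at one maximum per list (4.12, 3.64 and 4.16 in replicates 1, 2 and 3, and 4.21 in the pooled list). The deposited offset of the summit from the peak start, in bp, was used to place each summit. All replicate and pooled lists hold 30000 peaks, a round number that says nothing of how many sites were bound. The optimal list was found to be the 6580 peaks of the pooled list with the highest signal, so that its threshold acts as a threshold on pooled signal, with the lowest signal at 109.7, and every optimal peak sits at the capped q-value. Some optimal peaks share an interval and differ in summit, so that the 6580 peaks lie on 6453 distinct intervals, and 1 summit lies outside its interval. Each was kept as listed. Signals were used to rank peaks within a list and were not averaged or compared in size across lists. Replicates were compared by rank, since their lists have the same length. Replicate 2 had the lower cap and narrower peaks, with a median width of 430 bp against 464 and 456 bp in replicates 1 and 3.

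Coordinates are those of dm6, given counting from 1. The reference used was release 6 of the genome, the assembly called dm6, and the Ensembl release 115 annotation of it, after comparing arm names and finding that no peak ran past the end of its arm. Genes annotated as transposable elements were left out, which left 18164 genes on the main arms, 13945 of them protein-coding. The dm3 lists were used only as alternatives that need no sequence or annotation, and no coordinates were converted.

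N is the number of optimal peaks, 6580, and the N strongest peaks of each replicate list were compared. Peaks counted as shared when they overlapped by at least 1 bp. Random placements kept each peak's arm and width and avoided unknown sequence, 1000 times. They were uniform along each arm and did not keep to open chromatin or to sequence where peaks are often called. Each optimal peak was matched to the strongest overlapping peak in a replicate's whole list to give its rank there, and mean ranks with SD are over the 3 replicates. Promoter summits lay within 500 bp of the 5' end of any annotated transcript. Motifs were searched on both strands in the 101 bases centred on the summit and in a window of the same width centred 500 bp to the right, with the exact McNemar test on discordant peaks and 2000 bootstrap draws for intervals. A gene held a peak when an optimal summit lay in its body or within 1000 bp upstream, and gene lists were compared with 100000 random lists matched in 20 bins of length. A summit counted for a gene by this rule may lie nearer to the TSS of another gene. The random lists were drawn without regard to position, whereas some list members are close neighbours. The p-values of the gene lists treat such neighbours as independent. Differences of shares between sets of peaks were tested with 100000 permutations, and so were correlations. Peaks are not independent samples, so these p-values describe the lists and not the spread between embryos. Wilson intervals cover counting error only.

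The 18 gene lists, the 15 motifs, the tests and most alternatives were fixed before the data were examined. All 571 list members were matched to annotated genes, with 2 symbols (Dl and dys) read as Delta and dysf, a choice made after the annotation was seen and before any peak was assigned to a gene. The genes named are grn, the genes of the 25 strongest optimal peaks, up to 4 members of each list with the strongest peaks and up to 2 members with none, and the 5 genes with the most summits. A top peak was assigned to the gene whose body holds its summit, or else to the protein-coding gene with the nearest TSS. GATAd and Antp are named in addition, chosen after their values were seen, to complete short counts. The distances to the nearest GATA hexamer, the counts of 2 or more copies, the comparison of distal with promoter summits, the counts of pooled peaks by gene and the X share of pooled peaks below the optimal set were not among the comparisons fixed beforehand.

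The computations were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data. With 60.0% of 6580 peaks planted as shared, 61.4% were found, and a planted motif difference of 11.5 percentage points was recovered exactly. Of 200 random placements of 2000 peaks, 3% gave a motif p below 0.05. For gene lists among 13945 genes, 0.5% of 200 lists of long genes with no effect were called with length matching and 92.5% without it, while 52% of lists of 20 genes with odds of a peak raised 4-fold were called, so that short lists with real differences of that size are often missed. A planted Pearson correlation of 0.5 gave a Spearman value of 0.476.

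Alternatives covered the genome build, the overlap rule, the number of peaks taken, leaving out each replicate, the distance to a TSS, the motif form, window and control sequence, the rule that assigns peaks to genes, matching, and stronger subsets of peaks. For gene lists, leaving out a replicate means using optimal peaks that overlap one of the N strongest peaks of both others. Differences between groups of samples were not tested, since there is 1 group.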

Results

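The data were transcription factor ChIP-seq profiles of Grain, the product of grn, a zinc-finger protein of the GATA family known for its part in forming the posterior spiracles and in guiding motor axons. Embryos of Drosophila melanogaster aged 0 to 24 h, both sexes pooled, came from a transgenic line that makes Grain with a GFP tag at its C-terminus, and chromatin was pulled down with an antibody against GFP. The series had 1 group of 3 biological replicates and no second condition, so the questions it can answer are where the tagged protein was found, how well the replicates agreed, and which sequences and genes lay there. Each replicate was given as a list of 30000 ranked peaks on the dm6 genome, together with a pooled list of 30000 peaks and an optimal list of 6580 peaks that passed the authors' test of irreproducible discovery rate. The lists hold no read counts, so the sequencing depth behind a peak is unknown. Peak signal is the authors' own value, set separately in each list, and is used here only to rank peaks within a list.

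Most Grain peaks recurred across the replicates, and 67.8% of the optimal peaks were among the strongest of all 3. Of the 6580 optimal peaks, 5889 overlapped one of the 6580 strongest peaks of replicate 1 (89.5%, 95% Wilson interval 88.7 to 90.2), 5355 did so in replicate 2 (81.4%, 80.4 to 82.3) and 5767 in replicate 3 (87.6%, 86.8 to 88.4), a mean of 86.2% ± 4.25 (SD, n = 3). The optimal list holds the peaks with the highest signal in the pool of these same replicates, so that a high share is largely set by that choice. Peaks found in all 3 replicates numbered 4462 and had a median signal of 222.0, against 118.4 for the 557 peaks found in 1 replicate, and 27 optimal peaks were among the strongest peaks of no replicate. When the 6580 strongest peaks of each replicate were set against those of another, 77.6% ± 2.92 (SD over the 6 ordered pairs) were overlapped. Random placement within chromosome arms gave 4.05% (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Lists that share only open chromatin could exceed this uniform placement too, so the test does not speak to agreement particular to Grain. The pair of replicates 1 and 3 shared 80.9%, replicates 1 and 2 shared 77.2%, and replicates 2 and 3 shared 74.6%. Across optimal peaks, Spearman's rho of the replicates' signals was 0.78 for replicates 1 and 3, 0.75 for replicates 1 and 2, and 0.68 for replicates 2 and 3. In each of these 3 pairs the permutation p was 1e-05, raw and after Benjamini-Hochberg adjustment, the smallest that 100000 resamples can give. These correlations are across peaks, which are not independent replicates. The share of optimal peaks found per replicate depends on how many peaks are taken from each list, and was 18.5% with the 1000 strongest and 99.5% with all 30000.

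The hexamer bound by GATA factors, WGATAR (W is A or T, R is A or G), lay at the summits of Grain peaks. It was present within 50 bp of the summit in 3042 of 6580 optimal peaks (46.2%) and in 18.5% of the windows of the same width 500 bp to the right, a ratio of 2.504 and a difference of 27.8 percentage points (95% bootstrap interval 26.2 to 29.3; exact McNemar test, two-sided, p = 7.1e-254, adjusted p = 1.1e-252 over the 15 motifs). In the 6580 strongest peaks of each replicate the share at summits was 44.2% ± 0.672 (SD, n = 3) and the share in the flank was 18.4% ± 0.913, so the gap between summit and flank was far larger than the spread between replicates. At least 2 copies of the hexamer lay in 14.2% of summit windows and in 2.42% of flank windows. The median distance from a summit to the nearest copy within 500 bp was 48 bp, against 142 bp for randomly placed peaks. The GATA hexamer was commoner in the strongest peaks: 54.5% of the 1316 optimal peaks with the highest signal carried it, against 40.1% of the 1316 with the lowest, a difference of 14.4 percentage points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give).

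**Figure D1:**
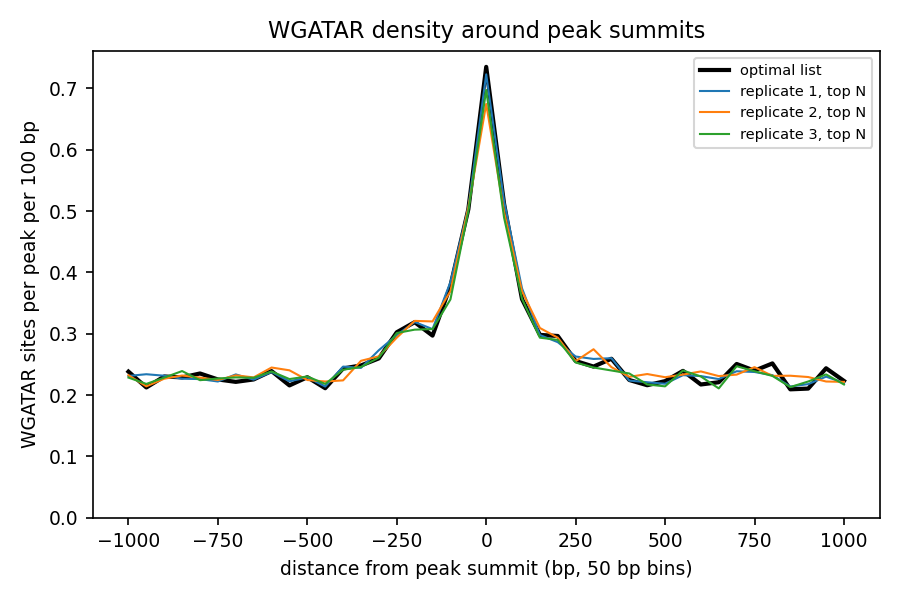
Density of WGATAR in sites per peak per 100 bp (vertical axis) against distance from the peak summit in bp, in 50 bp bins (horizontal axis), for the 6580 optimal peaks and the 6580 strongest peaks of each of the 3 replicates. The optimal peaks reach 0.735 at the summit and 0.223 at 500 bp to the right, and the replicates' curves lie close to them.

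Of the 14 other motifs fixed beforehand, few were enriched at summits. The core promoter element of DREF (TATCGATA), a factor of housekeeping promoters, was found in 1.34% of summit windows and 0.289% of flank windows (exact McNemar test, adjusted p = 3.7e-11). The core promoter element of M1BP (GGTCACAC) was found in 0.760% and 0.274% (exact test, adjusted p = 0.00039). The GAGA element was found in 15.02% and 12.3% (exact test, adjusted p = 1.6e-05), and the motif CCCTCT in 3.88% and 2.78% (adjusted p = 0.0013). The DREF element itself holds the letters GATA but was scored apart from WGATAR. The homeodomain core TAATTA was less frequent at summits than in the flank (5.76% against 6.85%, exact test, adjusted p = 0.018), as was the STAT motif (2.04% against 3.09%, adjusted p = 0.00040). Of 3 hexamers made by reordering the bases of WGATAR, 2 were less frequent at summits, at 14.0% against 16.0% and at 26.3% against 30.9% (exact test, adjusted p = 0.0029 and 2.1e-08), and the other missed the threshold at 19.0% against 20.4% (adjusted p = 0.071). The ratio of summit to flank was 0.877 and 0.850 for those 2 hexamers and 0.840 for TAATTA. A lower share of that size is thus not particular to the homeodomain core. The ratio of the STAT motif was lower, at 0.660. The motif of Zelda, an activator of early zygotic genes, was found in 1.73% and 1.37% (exact test, adjusted p = 0.13). The adjusted p of the exact test was 0.20 for the E box CATATG, 0.97 for the E box CAGCTG, 0.34 for the Grainyhead motif and 0.13 for the Runt motif.

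Grain peaks lay near transcription start sites (TSS) more often than chance placement gave, and a large part lay far from them. Summits of 2614 optimal peaks (39.7%, 95% Wilson interval 38.6 to 40.9) fell within 500 bp of an annotated TSS, against 13.6% for peaks placed at random on the same arms, a ratio of 2.91 (two-sided permutation test, p = 0.002, the smallest that 1000 placements can give). The share in the 6580 strongest peaks of each replicate was 40.5% ± 1.69 (SD, n = 3). Another 3213 optimal summits (48.8%) lay over 1000 bp from any TSS. The GATA hexamer was present at 50.5% of these distal summits and at 39.4% of the summits within 500 bp of a TSS, a difference of 11.2 percentage points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Both groups stood above their flanks, at 18.8% and 17.8%.

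The 25 strongest optimal peaks fell at 21 genes, and all 25 were among the 6580 strongest peaks of every replicate. Of these 25 summits, 14 carried the GATA hexamer within 50 bp, 13 lay in introns and 13 lay within 500 bp of a TSS. The strongest, at 9422699 to 9423332 on chromosome arm 3L (signal 2034; mean rank 1.33 ± 0.577, SD, n = 3), lay in an intron of Atat (FBgn0035989), which encodes an α-tubulin acetyltransferase, 243 bp from a TSS of aay. It was followed by a peak in the 5' UTR of CG9331 (FBgn0032889; 2L, 20823740 to 20824481; signal 1991; mean rank 1.67 ± 0.577, SD, n = 3). The next pair lay between genes on 3R, at 8206471 to 8207699 (signal 1597) and 8208298 to 8209294 (signal 1555), with CheA84a the nearest protein-coding TSS and grn the next protein-coding gene beyond it, 25362 and 27175 bp from its 5' end. This pair lies in the stretch of dense peaks around grn described below. Extra copies of the locus in the transgene may have raised their signal and rank. The gene u-shaped (ush, FBgn0003963), whose product is a partner protein of GATA factors, held 4 of the 25 peaks, all in its introns on 2L, at ranks 6, 8, 11 and 16. Among the others were peaks in introns of fz2, a Wnt receptor gene (signal 1304), sog, which encodes an antagonist of BMP signalling (signal 1122), and cno, which encodes the junction protein Canoe (signal 1070), and in the 5' UTR of Myd88, an adaptor of the Toll pathway (signal 1383). The remaining peaks were assigned to Top3beta, CG4313, Agpat4, HmgZ, hll, Atg17, Fa2h, Unc50, CG15673, CG17574, Fmr1, Muc68D and ana. The peak of cno was the least even across replicates, with ranks 17, 194 and 18.

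The genes with the most Grain summits were long. The gene body of ush and the 1000 bp upstream of it held 30 optimal summits, 16 of them with the GATA hexamer. The zinc-finger gene shn, which acts in Dpp signalling, held 22 summits, the zinc-finger gene jing held 21, bun held 20 and Svil held 18. Of 13945 protein-coding genes, 3556 (25.5%) held at least 1 summit, and these were longer, with a median length of 5544 bp, upstream part included, against 2823 bp for genes with none. Gene groups were therefore compared with random lists matched on length.

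Of 18 gene lists fixed beforehand, 4 held Grain summits more often than length-matched lists and 1 less often, at an adjusted p below 0.05 (two-sided permutation test with 100000 random lists, Benjamini-Hochberg over the 18 lists). In the list of gut and endoderm genes, 12 of 18 genes (66.7%) held a summit, against 4.68 by chance (permutation test, adjusted p = 0.0020). These included dpp (FBgn0000490), which encodes a BMP ligand (peak at 2L, 2454619 to 2455040, in its 5' UTR; signal 933; mean rank 51 ± 5.57, SD, n = 3), the forkhead factor gene fkh (signal 556; mean rank 391 ± 273, SD, n = 3), and the GATA factor genes srp (signal 549) and GATAe (signal 353), while hkb and alphaTry held none. With the 3290 peaks of highest signal alone, this call ended (permutation test, adjusted p = 0.12, range 0.00012 to 0.12 over the 8 alternatives fixed beforehand). It also ended in 3 alternatives chosen after seeing the data, where the excess of 40.7 percentage points became 23.4 with only peaks that carry the GATA hexamer, 6.99 with only peaks over 1000 bp from a TSS and 14.4 with the next 6580 pooled peaks (permutation tests, adjusted p = 0.091, 0.68 and 0.30). Peaks over 1000 bp from a TSS cannot lie in the 1000 bp upstream of a gene or in its first 1000 bp. The median length of the gut genes was 2650 bp, upstream part included, so that alternative could show little. Some gut genes are close neighbours, such as srp and GATAe on 3R and the trypsin genes around alphaTry on 2R. The test treated them as independent. Ribosomal protein genes held summits in 51 of 85 cases (60%), against 13.5 by chance (permutation test, adjusted p = 0.00018). Here 55 of the 56 summits lay within 500 bp of a TSS, and 14 carried the GATA hexamer. In the later alternatives the excess of 44.1 percentage points became 9.21, −0.491 and 10.4, and the call was kept only with peaks that carry the hexamer (permutation tests, adjusted p = 0.046, 1 and 0.065). The median length of the ribosomal protein genes was 2333 bp, upstream part included. The alternative with peaks over 1000 bp from a TSS could thus show little here too. RpL7 (signal 569), RpS27 (signal 527), RpL34b (signal 483) and RpL23A (signal 431) had the strongest peaks of that list, and RpL10 and RpL10Aa held none.

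In the list of genes of the posterior spiracle, an organ that needs grn to elongate, 17 of 22 held a summit (77.3%), against 10.3 by chance (permutation test, adjusted p = 0.027). The strongest peak of the list was that of cv-c (8 summits; strongest signal 413; mean rank 766 ± 286, SD, n = 3). It was followed by Stat92E, the transcription factor of the JAK/STAT pathway (8 summits; strongest signal 394; mean rank 881 ± 397, SD, n = 3), the POU factor gene vvl (1 summit, signal 345) and hh (3 summits, signal 336), while upd1 and dome, ligand and receptor genes of the JAK/STAT pathway, held none. In the tracheal list 11 of 14 held a summit (78.6%), against 6.04 by chance (permutation test, adjusted p = 0.041), among them tgo (signal 908; mean rank 48 ± 2.65, SD, n = 3), the FGF gene bnl (signal 401) and its antagonist gene sty (signal 318), and not the FGF receptor gene btl or kni. The tracheal list shares 4 genes with the spiracle list. Restricted to peaks found in a given pair of replicates, both calls ended in 2 of the 3 pairs: without replicate 1 the adjusted permutation p was 0.42 for the spiracle list and 0.14 for the tracheal list, and without replicate 3 it was 0.48 and 0.18. Without replicate 2 both calls were kept, at 0.041 and 0.011. The spiracle excess was 15.6, 27.5 and 14.9 percentage points without replicates 1, 2 and 3, against 30.5 with all, and the tracheal excess was 28.5, 41.5 and 28.0 points, against 35.4 with all. With peaks found in all 3 replicates both calls ended too, at 17.4 and 30.5 points (permutation tests, adjusted p = 0.29 and 0.093). Over the 8 alternatives the adjusted p ranged from 3.2e-06 to 0.49 for the spiracle list and from 0.00014 to 0.43 for the tracheal list, and each was called in 3 of the 8. The lowest p of each list came from Fisher's exact test without length matching, which is 1 of the 3 calls. With length matching the lowest were 0.00072 and 0.0017, with each peak assigned to the nearest TSS (permutation tests). Both calls also ended in the 3 later alternatives. With only peaks that carry the GATA hexamer, the tracheal excess went from 35.4 to 0.743 percentage points and the spiracle excess from 30.5 to 9.48 (permutation tests, adjusted p = 1 and 0.78). With only peaks over 1000 bp from a TSS the tracheal excess was 27.3 and the spiracle excess 18.5 points (permutation tests, adjusted p = 0.24 and 0.41). With the next 6580 pooled peaks they were 21.5 and 20.7 points (permutation tests, adjusted p = 0.27 and 0.16). Chemoreceptor genes were the list below chance, with 7 of 179 (3.91%) against 34.6 (permutation test, adjusted p = 0.00018). In that list Ir60b, Gr64a, Or88a and Ir68a had the strongest peaks, and Gr10a and Gr10b held none. The nearest protein-coding TSS to the peaks of Ir60b, Gr64a and Or88a belonged to Letm1, CG11594 and CG12402, so these peaks may belong to the neighbours. The chemoreceptor call was kept in the 8 alternatives fixed beforehand and in 2 of the later ones. With only peaks over 1000 bp from a TSS it ended, as the difference from chance went from −15.4 to −1.50 percentage points (permutation test, adjusted p = 0.43). Such peaks cannot lie in the 1000 bp upstream of a gene or in its first 1000 bp. The median length of these genes was 2691 bp, upstream part included, so this alternative could show little.

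All 6 genes of the list of GATA factors and their partner held a summit, against 3.17 by chance, which missed the threshold over the 18 lists (permutation test, raw p = 0.040, adjusted p = 0.10). Apart from ush and grn, these were pnr (1 summit, signal 666; mean rank 166 ± 48.2, SD, n = 3), srp (2 summits), GATAe (6 summits) and GATAd (2 summits). The count includes grn, where extra copies of the locus in the transgene may have raised the signal. The genes srp, GATAe and pnr lie close together on 3R, and the test treated them as independent. Without replicates 1, 2 and 3 the adjusted permutation p was 0.063, 0.048 and 0.067, and the list was called in 5 of the 8 alternatives, in a range of 0.00063 to 0.17. Genes of mature neuronal function held summits in 4 of 17 cases against 9.10 by chance (permutation test, adjusted p = 0.066), with elav, cpx, ChAT and onecut holding them and brp and Syt1 not. Without replicates 1, 2 and 3 the adjusted permutation p of that list was 0.10, 0.014 and 0.22, and it was called in 2 of the 8 alternatives, in a range of 0.014 to 1. The nearest protein-coding TSS to the strongest summits of cpx and ChAT belonged to MP1 and CG34283.

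**Figure D2:**
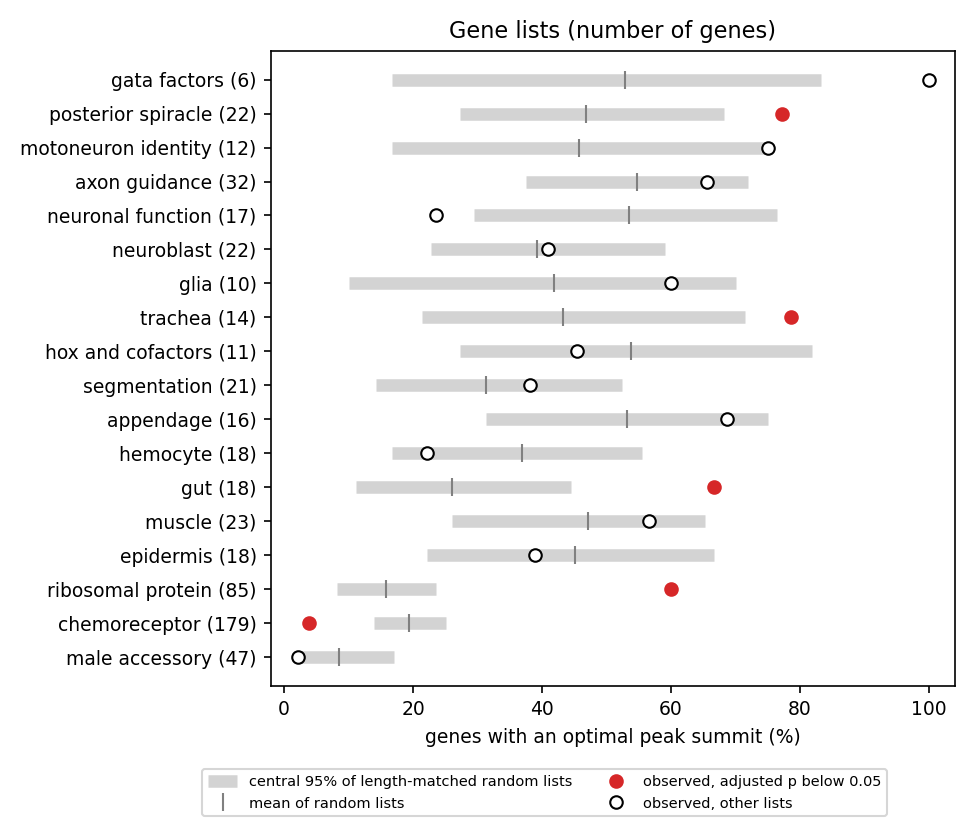
Share of genes with an optimal peak summit in the gene or the 1000 bp upstream, in percent (horizontal axis), for the 18 lists (vertical axis, number of genes in brackets), with the mean and the central 95% range of length-matched random lists. The gut list (66.7%), the ribosomal protein list (60%), the spiracle list (77.3%) and the tracheal list (78.6%) lie above their ranges and the chemoreceptor list (3.91%) below, as do the GATA factor list (100%, above) and the neuronal function list (23.5%, below), which missed the threshold after adjustment.

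The other 11 lists did not pass the test as fixed beforehand, and some passed it under another rule. With each peak assigned to the nearest TSS, the segmentation list stood 33.4 percentage points above chance, against 6.87 with the rule used here (permutation test, adjusted p = 0.0061, range 0.0061 to 0.98 over the 8 alternatives), and the appendage list 33.7 points, against 15.5 (permutation test, adjusted p = 0.028, range 0.00068 to 0.76). The low end of the appendage range came from Fisher's exact test without length matching. Without length matching (Fisher's exact test), the lists for axon guidance, motoneuron identity, glia, appendages and muscle passed above chance and that for the male accessory gland below. Of axon guidance genes, 21 of 32 held a summit against 17.51 by chance (permutation test, adjusted p = 0.45), and the strongest peaks lay in introns of Fas3 (signal 651), sli (signal 634; 9 summits), fra, the netrin receptor gene (signal 605; 7 summits), and Tl (signal 533), while Sema2a and PlexA held none. Of genes of motoneuron identity, 9 of 12 held a summit (permutation test, adjusted p = 0.15), led by hth, vvl, Lim3 and zfh1, and HGTX and VGlut held none. Of appendage genes, 11 of 16 held a summit (permutation test, adjusted p = 0.46), led by al, hth, Lim1 and mirr and without Dll and B-H1. Of glial genes, 6 of 10 held a summit (permutation test, adjusted p = 0.53), among them moody, pnt, gcm2 and loco and not repo or gcm. The peak at moody is the one that ranked 7 in the optimal list and also lies in CG4313. Of muscle genes, 13 of 23 held a summit (permutation test, adjusted p = 0.59), led by rols, twi, mbc and if and without bap and Mhc. Of segmentation genes, 8 of 21 held a summit (permutation test, adjusted p = 0.76), led by ptc (signal 663; mean rank 166 ± 7.37, SD, n = 3), opa, hh and hry and without hb and Kr. Of neuroblast genes, 9 of 22 held a summit (permutation test, adjusted p = 1), led by brat, Delta, insc and nub and without ac and sc. Of Hox genes and their cofactors, 5 of 11 held a summit (permutation test, adjusted p = 0.83): hth, lab, Ubx, Abd-B and Antp, while pb and Dfd held none. Of epidermal genes, 7 of 18 held a summit (permutation test, adjusted p = 0.83), led by m, sn, verm and serp and without ple and Ddc. Of hemocyte genes, 4 of 18 held a summit (permutation test, adjusted p = 0.45), namely ush, gcm2, crq and Pvr, and gcm and lz were among those with none. Of genes of the male accessory gland, 1 of 47 held a summit (permutation test, adjusted p = 0.32), namely Sfp26Ad, and Acp1 and Acp24A4 were among those with none. That summit lay in a 5' UTR and nearest to the TSS of Gpdh1. For fra, Lim3, twi, insc, m and sn too, the nearest protein-coding TSS to the strongest summit belonged to another gene. These were CG33752, CG17344, CG42741, sktl, CG9360 and sws, in that order.

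The grn locus itself was crowded with peaks. The gene lies on the minus strand of 3R at 8147368 to 8181444 (FBgn0001138), and 34 optimal summits fell in it or within 20000 bp on either side, more than in 99.99% of windows of the same width around other protein-coding genes, whose median was 4. In the strongest 6580 peaks of replicates 1, 2 and 3 the same window held 32, 37 and 34 summits. Of the 34 summits, 16 lay in introns of grn, 17 lay between genes, and 16 carried the GATA hexamer. The strongest peak inside the gene, at 8160373 to 8160903 in an intron, had a signal of 796 and a mean rank of 109 ± 61.1 (SD, n = 3). Upstream of the gene, stronger peaks lay at 8182715 to 8184077 (signal 901; mean rank 61 ± 31.2, SD, n = 3) and at 8187323 to 8188320 (signal 933; mean rank 65.3 ± 36.7, SD, n = 3). In the whole pooled list, 135 summits fell in the gene or within 50000 bp on either side, more than around any other protein-coding gene, where the median was 34 and the highest count 130. Neighbouring windows overlap, so the percentile is a description and not a test. Extra copies of the locus in the transgene may have raised the number and signal of peaks here, a candidate taken up in the last section.

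**Figure D3:**
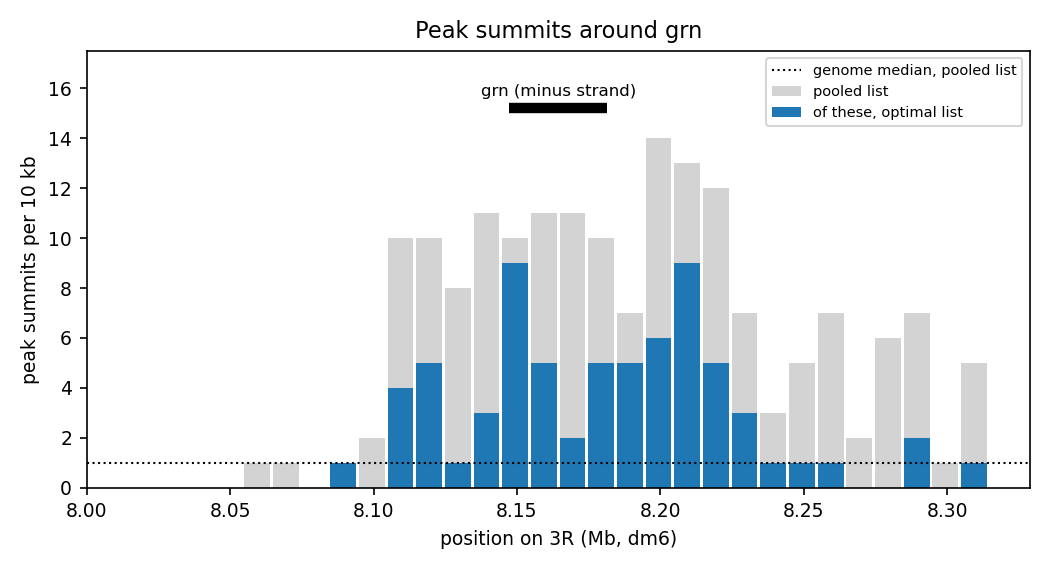
Peak summits per 10 kb (vertical axis) along 3R in Mb on dm6 (horizontal axis) around grn, for the pooled list (grey) and the part of it in the optimal list (blue), with the genome median of the pooled list as a dotted line. The 13 bins from 8104406 to 8234405 each hold 7 to 14 pooled summits, against a genome median of 1.

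Optimal peaks were fewer on the X chromosome. X held 925 optimal peaks, 39.4 per Mb, against 51.9 per Mb over the major autosomal arms, a ratio of 0.760, where arm 2L had 53.6, 2R 52.6, 3L 52.6 and 3R 49.3 per Mb. X thus held 14.1% of the peaks on the major arms (95% Wilson interval 13.3 to 14.9) and 17.7% of their length (exact binomial test, two-sided, p = 1.4e-15), and the share in the 6580 strongest peaks of each replicate was 13.7% ± 0.132 (SD, n = 3). The direction turned in the 23420 pooled peaks below the optimal set, where the X share was 18.6% (exact binomial test, two-sided, p = 0.00049). Both tests expect peaks in proportion to arm length alone. Both sexes were pooled and males carry fewer copies of X than of the autosomes, which could lower signal on X. As the optimal list is a cut on signal, the tests cannot tell this from fewer bound sites on X. The small chromosome 4 held 11 optimal peaks, 8.26 per Mb.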

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

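The test in this part was chosen only after the optimal list had been seen to be the top of the pooled list. The 23420 pooled peaks below the optimal set also carried the GATA hexamer above their flanks, at 28.5% of summit windows against 16.3% of the windows 500 bp to the right. The difference was 12.2 percentage points (95% bootstrap interval 11.4 to 12.9; exact McNemar test, two-sided, p = 1.4e-221). It is a signal in peaks that the authors' threshold left out. In steps of 2000 peaks by signal rank, the share at summits was 38.1% for ranks 6001 to 8000, 27.9% for ranks 18001 to 20000 and 21.2% for ranks 28001 to 30000, where the flank share was 15.9%. With 1 group and no control samples analysed here, no biological explanation was tested.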

How the results depend on the processing

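In this part, the 3 alternatives of the gene lists that restrict peaks to those with the GATA hexamer, to those over 1000 bp from a TSS, or to the next 6580 pooled peaks were chosen after seeing the data. Replicate agreement, signal correlation, promoter share, the GATA hexamer at summits and by signal, and the X share kept their direction and their side of the threshold in every alternative with a test, and the dm3 values lay within 1 SD of the main ones. The ranges were 63.9% to 80.9% for agreement, 0.68 to 0.78 for rho, 30.5% to 51.2% for the promoter share, 12.98 to 32.7 percentage points for the hexamer at summits, 9.73 to 15.3 by signal and 12.96% to 14.2% for X. The share of optimal peaks found in a replicate moved from 86.2% to 67.5% with reciprocal overlap of 50%, to 79.9% with summits within 100 bp, and to 18.5%, 73.8% and 99.5% with the 1000 strongest, 5 times as many and all replicate peaks, as the number taken sets what can be found. By construction, the count of optimal peaks became 3290 with a threshold at the median signal. The number of summits at grn was 61 with 50000 bp on either side, 16 in the gene body and 23 among the 3290 strongest peaks, since windows and lists were larger or smaller. The number of gene lists past the threshold moved most, from 5 to 8 with the nearest TSS, 3 with summits within 1000 bp of the gene's TSS, 12 without length matching, 3 with the 3290 strongest peaks, and 3 to 7 when 1 replicate was left out (3 without replicate 1, 7 without replicate 2, 3 without replicate 3). With peaks found in all 3 replicates it was 5 again, but the spiracle and tracheal lists dropped out (permutation tests, adjusted p = 0.29 and 0.093) and the lists of GATA factors and of neuronal function came in (0.039 for both). It was 2 with peaks that carry the hexamer, 0 with peaks over 1000 bp from a TSS (length-matched permutation test, 2 lists at an unadjusted p below 0.05) and 1 with the next 6580 pooled peaks. The loss of length matching may explain the rise to 12. Simulated lists of long genes with no effect were called in 92.5% of cases without it, before adjustment for the number of lists. For the others the cause was not tested. The ribosomal protein list went from 44.1 percentage points above chance to −0.491 with peaks over 1000 bp from a TSS, which removes the promoter peaks it rests on. At a median length of 2333 bp, upstream part included, these genes leave little room for such peaks, so this alternative could show little. Over the 8 alternatives fixed beforehand the ribosomal protein and chemoreceptor lists were called in 8, the gut list in 7, the list of GATA factors in 5, and the spiracle and tracheal lists in 3 each. Each of these counts includes the call of Fisher's exact test without length matching, which often called simulated lists of long genes with no effect. Depth is unknown, so no limit from depth can be given.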

Other observations

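The comparisons by annotated feature and by hexamer, and the tests on summits with the GATA hexamer, on ribosomal protein genes and on the share of the hexamer around grn, were chosen only after other results had been seen. By annotation, 3440 of 6580 optimal summits (52.3%) lay in introns, against 42.4% of randomly placed ones, and 752 (11.4%) lay in 5' UTRs, against 3.04% (two-sided permutation tests, adjusted p = 0.0024 for both). Coding sequence held 94 summits (1.43%), against 17.1% of random ones, and 3' UTRs held 125 (1.90%), against 4.86% (permutation tests, adjusted p = 0.0024 for both). Summits between genes made up 30.0%, against 30.8% of random ones, which missed the threshold (permutation test, adjusted p = 0.18). Of the 3966 summits over 500 bp from a TSS, 68.5% lay in introns. Among 2075 hexamers, both strands merged, that lay in at least 100 summit and flank windows together, the ratio of summit to flank ranked GATAAG first, in 25.8% of summit windows and 5.33% of flank windows. GCGATA followed, in 12.6% and 2.92%, and 9 of the 10 hexamers with the highest ratio held the letters GATA on one strand.

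A first pattern is the GATA hexamer at summits, for which base composition is a candidate explanation. The median ratio of summit to flank for 3 reordered hexamers of the same bases was 0.877, below the interval of the ratio of WGATAR itself (2.504, 95% bootstrap interval 2.36 to 2.65). This argues against base composition as its cause. No biological explanation was tested, since the design has 1 group, and binding by another GATA factor to the same sites stays open.

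A second pattern is the excess of promoter summits, for which open promoter chromatin pulled down without GATA sequence is a candidate explanation. Promoter summits carried the hexamer 21.5 percentage points above their flanks (95% bootstrap interval 19.2 to 24.0), less than the 31.8 of summits over 1000 bp from a TSS. The rule set beforehand asked for at least the distal value, so under it this test did not decide. A value of no excess over the flank lies outside this interval. Pull-down without GATA sequence would give no excess only if open promoters in general carry the hexamer no more often than their flanks. Promoters without a Grain peak were not examined, so this comparison cannot decide, and the explanation stays open. Summits with the hexamer lay within 500 bp of a TSS in 33.8% of cases and those without it in 44.8%. Promoter summits at the flank rate would give 18.8% for the former, already above the highest of 1000 random placements (15.71%). The random placements thus could not decide. The observed 33.8% lies above the 18.8% too, but this rests on the same counts as the comparison with the flanks. At ribosomal protein genes 25.0% of summits carried the hexamer (95% Wilson interval 15.5 to 37.7, which holds the flank share of promoters, 17.8%), against 39.7% of other promoter summits (permutation test, two-sided, p = 0.027). For the promoters of ribosomal protein genes, pull-down without GATA sequence may account for the peaks, but the wide interval does not settle it. With only peaks that carry the hexamer, these genes still stood 9.21 percentage points above length-matched lists (permutation test, adjusted p = 0.046). Recruitment through other proteins stays open as an untested alternative.

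The last pattern is the crowd of peaks at grn, for which extra copies of the locus in the transgene are a candidate explanation. The labels do not say how much of the locus the transgene carries, nor whether the control came from the same line. A control from that line would carry the extra copies too. The pooled list held 135 summits in the window of 50000 bp on either side, above the 99th percentile of other genes (83), as extra copies would give. The crowded stretch spans 130 kb, from 8104406 to 8234405, with 134 pooled summits, while the 50 kb to its left held 5 and the 50 kb to its right held 23. The pooled summits below the optimal set carried the hexamer in 16.2% of cases (95% Wilson interval 9.53 to 26.2), equal to their flanks at 16.2% and below the 28.5% of such summits elsewhere, whereas the optimal summits carried it in 45.9% of cases (34.0 to 58.3), far above their flanks at 13.1%. Raised background may thus account for the weaker peaks there but not by itself for where the stronger ones lie, and binding of Grain at its own gene stays open as an untested hypothesis for those.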
